A study of Mus musculus with 6 samples.

How the data were processed

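The samples were 6 droplet single-cell libraries of mouse ventricle without atria, 3 from HFpEF mice and 3 from CON mice. Per the labels, tissue was digested with collagenases II and IV at 37 °C, passed through a 40 µm strainer, freed of red cells and dead cells, and captured with the 10x Genomics 3' kit version 3.1. The labels do not say whether each library is a separate animal. They state the light cycle for both groups and no hour of collection. Bulk RNA samples named in the design were not analysed here.

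The deposited files hold UMI counts per gene and cell barcode for 32285 genes, made by Cell Ranger 6.0.1 per the file headers, on mm10 per the submitters' processing notes. The gene annotation release is not given in the sources used here. The counts are whole numbers without normalization, and no barcode had fewer than 500 UMIs. Total UMIs per library ran from 94751251 to 125903227 and barcodes from 12868 to 19945. Gene positions came from GENCODE M21 on GRCm38, matched by gene identifier.

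Cells with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept, which removed 11836 barcodes. Scrublet, as run through scanpy 1.11.5, called 2030 doublets, which were removed together with 290 cells of clusters that were mostly doublets; in CON replicate 3 it found no threshold of its own, and 0.422 was used. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 gave 38 clusters of at least 50 cells. The type of a cluster was the one with at least 3 fixed markers among its 10 leading genes, or otherwise the one with the highest share of its markers detected, in at least 25% of cells and at 2 times the median cluster. The cluster took that name when at least 3 markers of that type were detected, and otherwise stayed unnamed, as did a cluster of 153 cells with 7 mast cell markers among its leading genes. Clusters also stayed unnamed with more leading genes of another type, with no leading marker and under 0.333 of the library's median UMIs, or with under 3 leading markers and 60% of an unrelated type's markers. These thresholds were set after the data were seen. Names are of the form fibroblast-like, since the labels give no cell types.

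UMIs were summed per library and class. The 12 classes with at least 50 cells in every library were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test, R 4.3.3), with Benjamini-Hochberg adjustment over the genes of a class and a threshold of 0.05. Log2 fold changes are HFpEF over CON, as fitted. A prior count of 2 was used only for log2 CPM, as in the list tests. The difference of the effect between fibroblast-like and endothelial-like cells was tested as an interaction term. Across 31 gene lists, limma 3.58.1's camera with a preset correlation of 0.01 gave 87 list tests in the 3 main classes, adjusted together, beside camera with an estimated correlation and fry. Some of these lists hold transcripts typical of other cell types and served to look for contamination. The lists described in the text were chosen after the data were seen. Shares of cells were compared with exact two-sided permutation tests (scipy 1.17.1), whose smallest p with 3 against 3 libraries is 0.1, and with edgeR on cell counts. Errors are SD over libraries or the SE of the fit.

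Genes were named by a rule fixed beforehand: Angptl4; genes with an adjusted p under 0.05, a mean of at least 20 CPM and all 3 HFpEF libraries beyond all 3 CON libraries, up to 7 per direction in the main classes and 2 in the others, without predicted genes and contaminating transcripts; and up to 4 members of each list described, by smallest p. Other genes named were chosen after their values were seen.

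Angptl4 was also counted as the share of cells with at least 1 UMI after thinning each cell to 1000 UMIs, with 2000 UMIs and no thinning as alternatives. The steps were tested on simulated data made from the counts: at a simulated fold of 2 edgeR recovered 58.2% of changed genes in fibroblast-like, 64.2% in endothelial-like and 7.46% in macrophage-like cells, and at a fold of 4 87.9%, 93.9% and 86.4%. The simulation changed 200 genes per class. With fewer changed genes the adjustment over genes is stricter, so recovery may be lower in the real data. The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, sums thinned to the smallest library, a replicate block, Scrublet-called cells kept, at most 10% mitochondrial UMIs, at least 1000 UMIs per cell, Leiden resolution 2, and each library left out in turn; shares of named cells were added after the data were seen.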

Results

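Ventricular cells were profiled by droplet single-cell RNA sequencing in a mouse model of heart failure with preserved ejection fraction (HFpEF). Male C57BL/6N mice, 8 weeks old at the start, received a high-fat diet and L-NAME, an inhibitor of nitric oxide synthases, at 0.5 g/L in the drinking water (HFpEF), or normal diet and water (CON), for 5 weeks. There were 6 libraries of ventricle without atria, 3 HFpEF and 3 CON. The labels do not say whether each library came from 1 mouse, so the p-values measure the spread between these libraries, which may be technical. The matrices held 93405 barcodes, with 12868 to 19945 barcodes and 94751251 to 125903227 unique molecular identifiers (UMIs) per library. After filters and doublet removal 79249 cells remained, of which 62554 fell into 17 classes named after their marker genes and 16695 stayed unnamed.

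CON replicate 3 stood apart in depth. Its analysed cells had a median of 2605 UMIs, against 6298 to 9013 in the other 5 libraries, and 46.6% of its cells stayed unnamed, against 9.30% to 16.6%. Unnamed cells made up 25.8% ± 18.0 of CON cells and 12.2% ± 3.04 of HFpEF cells (SD, n = 3 libraries per group). Class names were rebuilt here from fixed markers, and the thresholds that left clusters unnamed were set after the data were seen.

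The series title names ANGPTL4 as a link between fibroblasts and angiogenesis, so Angptl4 was followed first. Angptl4 (ENSMUSG00000002289; GRCm38 chromosome 17, 33773750 to 33781830, minus strand, protein-coding with 4 annotated transcripts) encodes a secreted inhibitor of lipoprotein lipase that is induced by fatty acids through PPARs. In fibroblast-like cells it averaged 30.5 ± 5.67 CPM (UMIs scaled to equal library totals) in CON and 114 ± 20.6 CPM in HFpEF (SD, n = 3 libraries per group), from 1516 to 2000 and 5972 to 11633 UMIs per library. Endothelial-like cells had 42.7 ± 14.1 CPM in CON and 181 ± 68.7 CPM in HFpEF. Pericyte-like cells, the mural cells of capillaries, had 37.8 ± 8.89 and 108 ± 8.34 CPM.

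All 3 HFpEF values of Angptl4 lay above all 3 CON values in each of the 6 classes where it was tested: fibroblast-like, endothelial-like, pericyte-like, glial-like, lymphatic endothelial-like and smooth muscle-like cells. In macrophage-like, B-cell-like, T-cell-like, endocardial-like, monocyte-like and neutrophil-like cells its counts did not pass the filter, and the groups overlapped. In monocyte-like cells it averaged 6.18 CPM in CON and 5.51 CPM in HFpEF. The log2 fold changes were 1.90 (SE 0.18) in fibroblast-like, 2.08 (SE 0.32) in endothelial-like, 1.49 (SE 0.24) in pericyte-like, 1.88 (SE 0.49) in glial-like, 1.45 (SE 0.37) in lymphatic endothelial-like and 1.57 (SE 0.35) in smooth muscle-like cells. Adjusted over all genes of a class, edgeR's quasi-likelihood test called Angptl4 in pericyte-like cells (adjusted p = 0.0424). In fibroblast-like cells it ranked 1st of 15439 genes without passing (adjusted p = 0.0605). In endothelial-like cells it ranked 6th of 11266 (adjusted p = 0.364). The edgeR adjusted p was 0.278 in glial-like, 0.388 in lymphatic endothelial-like and 0.187 in smooth muscle-like cells; in the last DESeq2 called it (0.000271), and in lymphatic endothelial-like cells edgeR without the low-count filter did (0.00278). Angptl4 was fixed as a gene of interest before the data were examined here. It was taken from the title of this same series, which may rest on these libraries. The choice is thus not independent of them, and p-values for this gene alone are not those of a separate prediction. Adjusted over the 6 tested classes for this gene alone, the edgeR p-values ran from 2.35e-05 in fibroblast-like cells to 0.0070 in glial-like cells. DESeq2 called it in fibroblast-like (adjusted p = 2.28e-18) and endothelial-like cells (adjusted p = 4.02e-10, with 2 of 15 alternatives calling it and a range from 4.02e-10 to 0.9999). Over the 15 alternatives the adjusted p in fibroblast-like cells ranged from 2.28e-18 to 0.341 and the log2 fold change from 1.76 to 2.04. Of these alternatives 4 called it, among them the fit without HFpEF replicate 1 (adjusted p = 0.0484). In pericyte-like cells 5 of 15 alternatives called it (adjusted p from 0.000195 to 0.332), and the call ended without HFpEF replicate 1 (adjusted p = 0.143), 2 (0.275) or 3 (0.242) and without CON replicate 1 (0.332) or 3 (0.0997), by DESeq2 (0.0715), with thinned sums (0.113), with at most 10% mitochondrial UMIs (0.309) and with at least 1000 UMIs per cell (0.0910). With a replicate block edgeR called 1 gene in pericyte-like cells, against 2 without it. In glial-like cells the fit without CON replicate 3 gave a log2 fold change of 2.84 and an adjusted p of 0.000460, where the 15 alternatives ran from 3.56e-06 to 0.826.

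**Figure D1:**
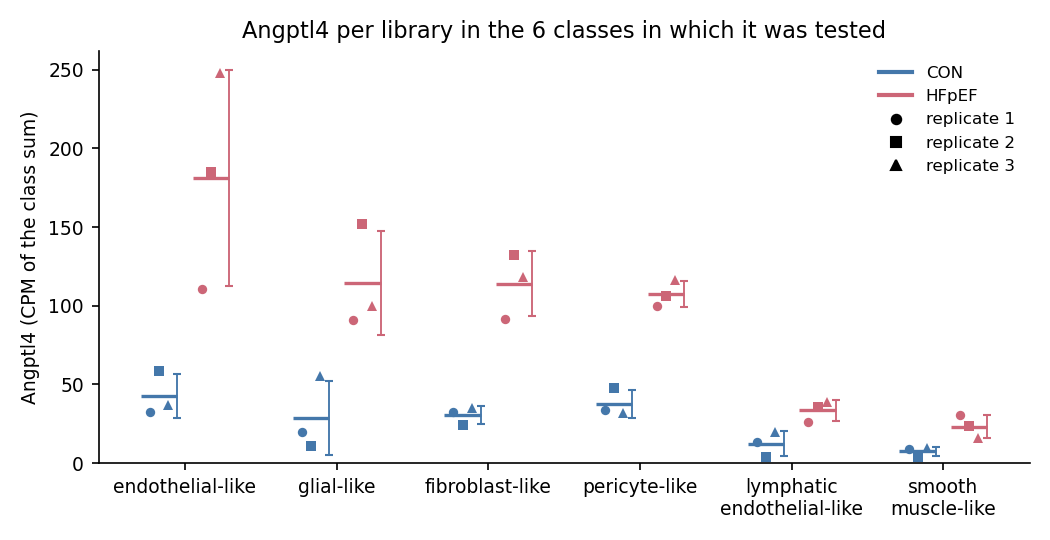
Angptl4 in CPM (y axis, linear scale) per library and cell class, with CON and HFpEF libraries as separate points and group means as bars. In fibroblast-like cells the CON libraries lay between 24.1 and 34.9 CPM and the HFpEF libraries between 91.7 and 132 CPM.

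The share of fibroblast-like cells with at least 1 Angptl4 UMI, after every cell was thinned to 1000 UMIs, was 2.33% ± 0.313 in CON and 8.79% ± 1.19 in HFpEF (SD, n = 3 libraries per group; exact two-sided permutation test p = 0.1, the smallest that 3 against 3 libraries can give). Thinning left out 190 CON and 184 HFpEF cells, the median depths were 9393 and 10504 UMIs, and unthinned the shares were 13.1% ± 2.28 and 39.4% ± 5.60. B-cell-like cells, which should lack Angptl4, showed a thinned share of 0.299% ± 0.517 in CON and 0.644% ± 0.30 in HFpEF at median depths of 3245.5 and 3351.5 UMIs. Thinned endothelial-like cells had shares of 3.22% ± 1.45 and 10.4% ± 1.84. Of 20 named clusters with at least 50 cells in every library, 14 had all HFpEF values above all CON values; the clusters share libraries and free RNA, so they do not count as separate evidence. These included the 6 fibroblast and 3 endothelial clusters. Of the endothelial clusters 1 averaged 378 CPM in HFpEF and the others 19.7 and 18.2 CPM.

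In fibroblast-like cells, the matrix-producing cells of the ventricle, camera called lists of cell division higher and antioxidant defence lower in HFpEF, calls that were lost with an estimated correlation, and did not call the activation genes of fibroblasts. Of 22 cell cycle genes 22 had a log2 fold change above 0 (median 1.02), and all 8 tested genes of MHC class II antigen presentation were higher (median 0.53). Of 26 oxidative stress genes 19 were lower (median −0.14), as were all 13 mitochondrially encoded genes (median −0.12). These 4 lists were called by limma's camera, at adjusted p = 8.34e-09 for cell cycle, 0.000119 for MHC class II, 0.00294 for oxidative stress defence and 0.00574 for mitochondrially encoded genes. With an estimated correlation none was called: the adjusted p was 0.705 for cell cycle, 0.694 for MHC class II, 0.694 for oxidative stress defence and 0.720 for mitochondrially encoded genes. The mitochondrially encoded list lost its camera call without CON replicate 1 (adjusted p = 0.237). H2-Aa and other members of the MHC class II list were leading genes of the dendritic-like cluster. Its cells made up 0.130% ± 0.105 of analysed cells in CON and 0.603% ± 0.557 in HFpEF, with overlap. Myeloid contaminating transcripts took 0.336% ± 0.0200 and 0.341% ± 0.0865 of fibroblast-like UMIs. Whether RNA carried over from antigen-presenting cells raised this list was not tested. A cluster of dividing fibroblast-like cells held 202 cells, 143 of them from HFpEF replicate 2; without that library the camera adjusted p of the cell cycle list was 2.20e-05.

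No single gene passed in fibroblast-like cells at an adjusted p under 0.05 among 15439 tested by edgeR, with 0 higher and 0 lower; 732 had an unadjusted p under 0.05, and DESeq2 called 9 higher and 22 lower. All 3 libraries of a group lay beyond those of the other for 9.91% of genes, where chance gives 10%. Adjusted over the list alone, 2 of 36 tested PPAR target and fatty acid genes rose, Angptl4 and Cpt1a (log2 fold change 0.68, SE 0.094, edgeR adjusted p over the list alone 0.00111, over all genes 0.195). Cpt1a encodes the carnitine transferase that admits long-chain fatty acids to mitochondria; 22 of the 36 genes of this list were higher, and camera did not call it (adjusted p = 0.161; without CON replicate 2 it was called, 0.0460). In the fry test for changes in either direction this list had an adjusted p of 0.00472. Adjusted over the list alone, 2 oxidative stress genes fell, Srxn1 (sulfiredoxin, log2 fold change −0.60) and Hmox1 (heme oxygenase, −0.72), each with an edgeR adjusted p of 0.0488, and over all genes 0. Among cell cycle genes 0 passed adjusted over the list alone or over all genes by edgeR. Ccnb2, a mitotic cyclin, had a log2 fold change of 1.14 (SE 0.32) and Top2a, a topoisomerase of dividing cells, 1.57 (SE 0.50). Levels were low (Top2a 2.90 ± 0.945 CPM in CON and 8.49 ± 6.54 in HFpEF). The MHC class II genes H2-Aa (0.64, SE 0.26) and Cd74 (0.51, SE 0.27) did not pass either.

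Among genes that act on vessels, camera called those that promote angiogenesis lower in fibroblast-like cells, a call that was lost with an estimated correlation, and did not call those that restrain it. Of 27 genes that restrain angiogenesis 16 were higher (camera adjusted p = 0.167), and 1 rose adjusted over the list alone, Angptl4, with 0 over all genes; camera called this list without HFpEF replicate 2 (adjusted p = 0.0123) or CON replicate 3 (0.0403). Of 40 tested genes that promote angiogenesis 24 were lower (camera adjusted p = 0.0186; adjusted p = 0.720 with an estimated correlation), and the call ended without HFpEF replicate 1 (0.0969), HFpEF replicate 2 (0.213) or CON replicate 3 (0.288). Its leading members, Sox18 (log2 fold change −1.07), Flt1 (−0.45), Dll4 (−0.82) and Erg (−1.26), are genes of endothelial cells, and the fixed list of endothelial contaminating transcripts was also lower in these sums, 8 of 8 genes (camera adjusted p = 0.0158; adjusted p = 0.694 with an estimated correlation). Those transcripts made up 0.0206% ± 0.00690 of UMIs in CON and 0.0152% ± 0.00245 in HFpEF.

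Of 17 collagen genes 13 were higher, led by Col6a3 (log2 fold change 0.63, SE 0.23) and Col15a1 (0.69, SE 0.29), with 0 passing over all genes and 0 adjusted over the list alone by edgeR. Camera called the collagens (adjusted p = 0.0279; adjusted p = 0.736 with an estimated correlation), and the call ended without HFpEF replicate 2 (0.829) or CON replicate 2 (0.464). The fibroblast activation list, with Postn and other markers of stressed or injured matrix cells, was not called (16 of 30 genes higher, median log2 fold change 0.03, mean −0.0035, camera adjusted p = 0.893). Camera also called nuclear genes of oxidative phosphorylation higher (41 of 49, adjusted p = 0.0279; adjusted p = 0.824 with an estimated correlation), a call that ended without HFpEF replicate 2 (0.981, lower), CON replicate 1 (0.102) or CON replicate 2 (0.411). Inflammatory cytokines and NF-kB feedback genes were called higher (16 of 22, adjusted p = 0.0227; adjusted p = 0.720 with an estimated correlation), and the call ended without HFpEF replicate 2 (0.117), HFpEF replicate 3 (0.0573) or CON replicate 2 (0.426). Genes of cholesterol and fatty acid synthesis were called lower (21 of 25, adjusted p = 0.0189; adjusted p = 0.736 with an estimated correlation), and that call ended without HFpEF replicate 1 (0.184), HFpEF replicate 3 (0.105), CON replicate 2 (0.267) or CON replicate 3 (0.720). The cardiomyocyte contaminating transcripts were called lower in the same sums (13 of 16, adjusted p = 0.000516; adjusted p = 0.720 with an estimated correlation).

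In endothelial-like cells camera called lists of circadian clock, interferon response and fatty acid genes higher in HFpEF, calls that were lost with an estimated correlation, and clock genes moved in both directions. Of 17 clock genes 7 rose and 2 fell adjusted over the list alone, and 0 over all genes, in edgeR's test. Those that rose included Hlf, a clock output factor (14.1 ± 2.09 CPM in CON, 29.6 ± 3.26 in HFpEF; log2 fold change 1.05, SE 0.16, adjusted p over the list alone 0.00112), and the repressors Per3 (0.997, SE 0.21) and Per2 (0.84, SE 0.19), both at 0.00412. Arntl, which encodes the core activator BMAL1, fell by 1.04 (SE 0.23) on the log2 scale at an adjusted p of 0.00412 over the list alone. Of 33 interferon-stimulated genes 30 were higher (median log2 fold change 0.40), among them Ifit2 (0.92, SE 0.29) and the chemokine Cxcl10 (1.38, SE 0.50), while 0 passed adjusted over the list alone or over all genes by edgeR.

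Camera called the clock list (adjusted p = 0.000155), the interferon list (8.34e-09) and the PPAR target and fatty acid list (0.00308); with an estimated correlation the adjusted p was 0.694, 0.719 and 0.694. The clock and interferon lists were called with any 1 library left out, and the fatty acid list lost its call without CON replicate 3 (0.146). Of 34 tested PPAR target and fatty acid genes 7 rose and 1 fell adjusted over the list alone, and 0 over all genes. Beside Angptl4 these were Pdk4, which restrains glucose oxidation (log2 fold change 1.54, SE 0.31, edgeR adjusted p over the list alone 0.0128), Ucp2, a mitochondrial carrier (0.78, SE 0.18, 0.0143), the lipid droplet protein Plin2 (0.91, SE 0.22, 0.0191), Cpt1a (0.58, SE 0.16, 0.0257), Acot2 and Slc25a20. The desaturase gene Scd2 fell by 0.84 (SE 0.20, 0.0191).

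**Figure D2:**
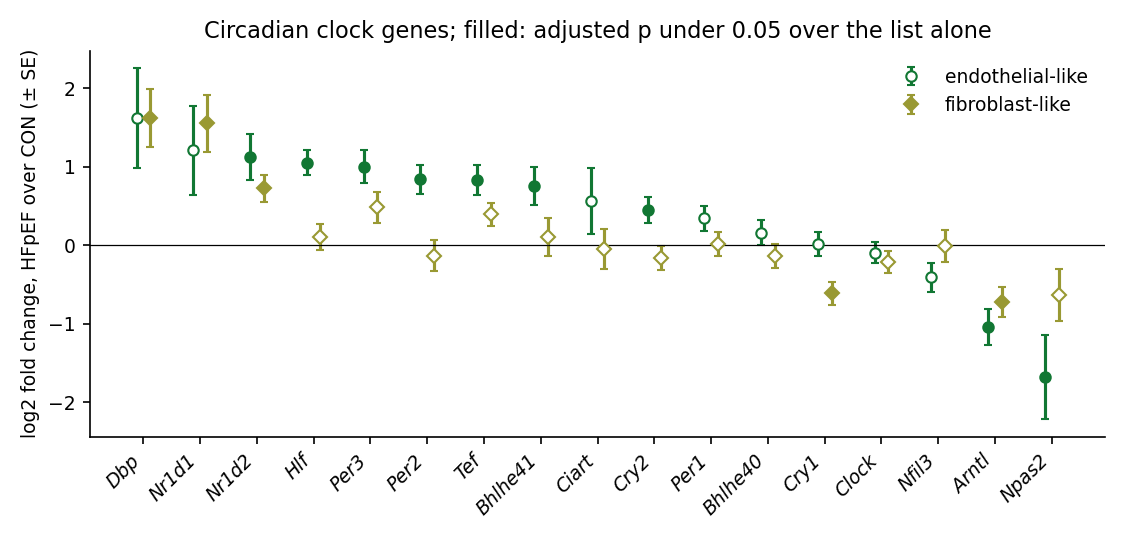
Log2 fold change (y axis, HFpEF over CON, with standard errors) of circadian clock genes (x axis) in endothelial-like and fibroblast-like cells, filled where the adjusted p over the list alone was under 0.05. In endothelial-like cells Hlf stood at 1.05 and Arntl at −1.04; in fibroblast-like cells Nr1d2 stood at 0.72 and Cry1 at −0.62.

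Across all 11266 genes tested in endothelial-like cells edgeR called 0 higher and 0 lower, with 590 at an unadjusted p under 0.05 and 10.9% without overlap between the groups, where chance gives 10%; DESeq2 called 5 higher and 8 lower. With the replicate number as a block edgeR called 17 higher and 18 lower; whether the numbers pair the libraries is not known. Without CON replicate 2 or CON replicate 3 edgeR called 4 and 11 genes. Genes that promote angiogenesis (28 of 41 higher, camera adjusted p = 0.0801) and those that restrain it (14 of 24 higher, 0.0883) were not called, and of the latter 2 rose adjusted over the list alone, Angptl4 and Adamts8 (log2 fold change 1.29, SE 0.34), with 0 over all genes. Camera called the first without CON replicate 3 (0.0350) and the second without CON replicate 1 (0.0179). Nitric oxide and cGMP genes, the pathway that L-NAME inhibits, were not called (12 of 20 higher, adjusted p = 0.278), nor were endothelial activation and leukocyte adhesion genes (11 of 17 higher, 0.290; without CON replicate 3, 0.0143).

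The other lists that camera called in endothelial-like cells were lost with an estimated correlation and depended on single libraries. The unfolded protein response was higher (21 of 26 genes, adjusted p = 0.0129; adjusted p = 0.694 with an estimated correlation; ended without HFpEF replicate 2, 0.0793, HFpEF replicate 3, 0.0506, or CON replicate 1, 0.0550). Mitochondrially encoded genes were higher (11 of 13, 0.0252; adjusted p = 0.736 with an estimated correlation), and the call ended without HFpEF replicate 1 (0.0901), HFpEF replicate 3 (0.222), CON replicate 2 (0.349) or CON replicate 3 (0.20). Oxidative stress defence was lower (15 of 24, 0.0287; adjusted p = 0.694 with an estimated correlation), and the call ended without HFpEF replicate 2 (0.127), CON replicate 1 (0.0583) or CON replicate 3 (0.0644). Dissociation and immediate early genes were higher (21 of 31, 0.0487; adjusted p = 0.736 with an estimated correlation), and the call ended without HFpEF replicate 1 (0.140), HFpEF replicate 3 (0.222), CON replicate 1 (0.299) or CON replicate 3 (0.288). Cardiomyocyte contaminating transcripts were higher in the same sums (13 of 15, camera adjusted p = 9.72e-06; adjusted p = 0.720 with an estimated correlation) and fibroblast contaminating transcripts lower (7 of 8, 0.0252; adjusted p = 0.720 with an estimated correlation). The neutrophil transcripts S100a8 (log2 fold change −3.16) and S100a9 (−3.02) were lower in these endothelial-like sums, adjusted p = 0.00135 over the list of myeloid contaminating transcripts alone by edgeR.

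In fibroblast-like cells 3 clock genes rose and 2 fell adjusted over the list alone, and 0 over all genes. These were Dbp (log2 fold change 1.62, SE 0.37), Nr1d2 (0.72, SE 0.17) and Nr1d1 (1.55, SE 0.36) against Cry1 (−0.62, SE 0.15) and Arntl (−0.72, SE 0.19). The edgeR adjusted p-values over the list alone were 0.0117 for the first 4 and 0.0154 for Arntl. As a list the clock genes had no common direction there (median −0.04, mean 0.12, camera adjusted p = 0.837). Whether the HFpEF effect differed between fibroblast-like and endothelial-like cells was tested by an interaction term over 15069 genes, and edgeR called 0 (1075 at an unadjusted p under 0.05; the smallest adjusted p was 0.117). The difference for Angptl4, endothelial minus fibroblast, was 0.13 on the log2 scale (SE 0.39, adjusted p = 0.958), and for Hlf 0.92 (SE 0.21, adjusted p = 0.490).

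In macrophage-like cells camera called lists of recruited and lipid-associated macrophages higher and of the matrix lower in HFpEF, calls that were lost with an estimated correlation, and 0 genes passed over all genes by edgeR. Of 16 recruited and lipid-associated macrophage genes 14 were higher (median log2 fold change 0.71), led by Vim, an intermediate filament of migrating cells (0.60, SE 0.27), the galectins Lgals3 (1.03) and Lgals1 (0.79), and Lpl, lipoprotein lipase (0.60). Camera called the list (adjusted p = 0.000125; adjusted p = 0.719 with an estimated correlation) also with any 1 library left out. Nuclear genes of oxidative phosphorylation were higher in 48 of 49 (9.90e-06; adjusted p = 0.720 with an estimated correlation; without HFpEF replicate 2, 0.132) and mitochondrially encoded genes lower in 12 of 13 (0.000994; adjusted p = 0.694 with an estimated correlation). HFpEF replicate 2 gave 535 of the 860 HFpEF macrophage-like cells. Median depths were 7280, 6487.5 and 2485 UMIs in CON replicates 1, 2 and 3, and 9065, 12504 and 7935.5 in HFpEF. Depth thus differed between the groups without overlap, and whether it shaped the list calls in this class was not tested.

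Fibroblast activation genes were lower in macrophage-like cells in 15 of 21 (9.90e-06; adjusted p = 0.694 with an estimated correlation). Of these 3 fell adjusted over the list alone and 0 over all genes by edgeR: Comp, a cartilage matrix protein (log2 fold change −2.58, SE 0.34), Loxl2 (−1.47, SE 0.37) and Ltbp2 (−2.58, SE 0.66). Matrix glycoproteins and proteoglycans were lower in 22 of 25 genes (camera adjusted p = 3.25e-07; adjusted p = 0.720 with an estimated correlation). Collagens were lower in 12 of 14 (0.0309; adjusted p = 0.744 with an estimated correlation), a call that ended without HFpEF replicate 3 (0.457, higher), CON replicate 2 (0.279) or CON replicate 3 (0.341). The 8 fibroblast contaminating transcripts were lower in the same sums (8 of 8, 0.00953; adjusted p = 0.720 with an estimated correlation), though their share of UMIs overlapped (0.473% ± 0.176 in CON and 0.304% ± 0.270 in HFpEF, with HFpEF replicate 1 the highest of the 6 libraries at 0.607%), as were endothelial (5 of 6, 0.0233; adjusted p = 0.694) and myeloid contaminating transcripts (7 of 8, 0.000207; adjusted p = 0.694), the last led by S100a9 (log2 fold change −3.81) and S100a8 (−2.16).

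Resident macrophage genes were lower in 13 of 14 (camera adjusted p = 0.0480; adjusted p = 0.719 with an estimated correlation), among them Lyve1 (log2 fold change −1.20) and Gas6 (−0.58). The call ended without any of HFpEF replicate 1 (0.0901), 2 (0.153), 3 (0.183) and CON replicate 1 (0.264) or 2 (0.314). Glycolysis genes were higher in 12 of 15 (0.0129; adjusted p = 0.720 with an estimated correlation; ended without HFpEF replicate 2, 0.160, or CON replicate 2, 0.279) and immediate early genes lower in 27 of 31 (0.00141; adjusted p = 0.736 with an estimated correlation; ended without HFpEF replicate 2, 0.509, or CON replicate 2, 0.464). Of 7253 genes edgeR called 0 higher and 0 lower in macrophage-like cells (274 at an unadjusted p under 0.05, 8.09% without overlap against 10% by chance), and DESeq2 called 0 higher and 4 lower. Over the 3 main classes camera called 32 of 87 list tests, 15 higher and 17 lower. Other splits of the same 6 libraries into 3 against 3 gave 16 to 33 camera calls. A camera call alone thus does not show an effect of HFpEF. With an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05, and fry's directional test called 0, with 5. Fry's test for changes in either direction called 2, the fibroblast list of PPAR targets given above and the endothelial contaminating transcripts in macrophage-like cells (adjusted p = 0.0128).

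Among the 9 other classes tested, glial-like cells, the Schwann cells of cardiac nerves, had 11 genes higher and 35 lower. This was the highest count by edgeR with all 6 libraries and Scrublet-called cells removed. DESeq2 called 12 and 51 there, and 42 and 141 in smooth muscle-like cells. Without CON replicate 1 edgeR called 33 glial-like and 36 smooth muscle-like genes, and without CON replicate 2 26 and 33. Ucp2 rose from 19.0 ± 4.06 to 71.7 CPM (log2 fold change 1.94, SE 0.25, adjusted p = 0.000740) and the clock repressor Per3 from 13.7 ± 0.816 to 48.6 CPM (1.80, SE 0.34, 0.0244). Igfbp6, which binds insulin-like growth factors, fell from 147 ± 34.7 to 33.4 CPM (−2.14, SE 0.24, 0.000245), and Has1, a hyaluronan synthase, fell by 1.85 on the log2 scale (SE 0.32, 0.0314). Fibroblast contaminating transcripts made up 1.34% ± 0.0702 of glial-like UMIs in CON and 0.826% ± 0.185 in HFpEF (n = 3 libraries per group). Lymphoid contaminating transcripts rose from 0.000978% ± 0.000801 to 0.0130% ± 0.00738, and Igkc, an immunoglobulin transcript of B cells, was among the 11 higher genes (log2 fold change 5.22, edgeR adjusted p = 0.0113; ended without HFpEF replicate 2, 0.0870, or CON replicate 2, 0.0582, and with Scrublet-called cells kept, 0.826). Ucp2 was called in all 15 alternatives; Igfbp6 lost its call when Scrublet-called cells were kept (log2 fold change −0.91, adjusted p = 0.826). Has1 lost it without HFpEF replicate 1 (0.0527), 2 (0.0873) or 3 (0.109) or CON replicate 3 (0.0576), with Scrublet-called cells kept (0.926) and with at least 1000 UMIs per cell (0.0923), and Per3 without HFpEF replicate 1 (0.107) or 2 (0.0870) or CON replicate 1 (0.0735), 2 (0.0582) or 3 (0.0514), with Scrublet-called cells kept (0.152) and with at most 10% mitochondrial UMIs (0.140). Keeping the Scrublet-called cells lowered the glial-like calls from 46 to 2; with 1 library left out they ranged from 13 to 60, and the low counts were those without HFpEF replicate 2 (13), HFpEF replicate 3 (22) and CON replicate 2 (26).

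**Figure D3:**
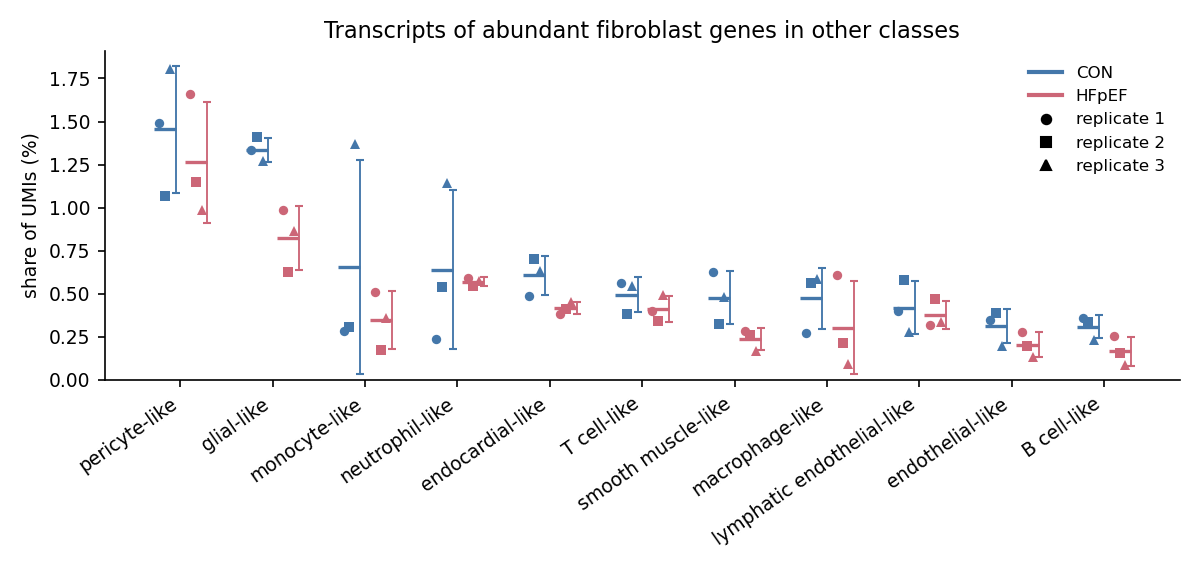
Share of UMIs (y axis, percent) taken by 8 fibroblast contaminating transcripts in each class other than fibroblast-like cells, with 1 point per CON or HFpEF library. In glial-like cells the CON libraries lay between 1.27% and 1.41% and the HFpEF libraries between 0.625% and 0.989%.

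In B-cell-like cells 1 gene rose and 10 fell (DESeq2: 4 and 17). Ccl4, a chemokine for monocytes and T cells, rose from 6.84 ± 0.790 to 39.8 CPM (log2 fold change 2.55, SE 0.32, edgeR adjusted p = 0.00118) and was called in all 15 alternatives. Hk2, a hexokinase, fell from 60.9 ± 15.6 to 18.7 CPM (−1.67, SE 0.23, 0.00322) and Has1 from 38.2 ± 16.9 to 10.1 CPM (−1.74, SE 0.31, 0.0235). Fibroblast contaminating transcripts took 0.310% ± 0.0674 of B-cell-like UMIs in CON and 0.166% ± 0.0850 in HFpEF. Hk2 lost its call without HFpEF replicate 3 (0.0561) and Has1 without HFpEF replicate 3 (0.0891) or CON replicate 1 (0.121); both lost it at Leiden resolution 2 (0.829 and 0.644) and with Scrublet-called cells kept (0.9999 each), and each of these 2 settings left 1 gene called. Without HFpEF replicate 3 or CON replicate 1 the B-cell-like count was 1 or 2, and without HFpEF replicate 1, HFpEF replicate 2 or CON replicate 3 it was 30, 18 or 21.

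In endocardial-like cells, the lining of the chambers, Inhba rose from 148 ± 22.6 to 387 CPM (log2 fold change 1.39, SE 0.21, edgeR adjusted p = 0.0274). Inhba encodes the activin A subunit; the call ended without HFpEF replicate 1 (0.294), HFpEF replicate 3 (0.279) or CON replicate 2 (0.109) and with at most 10% mitochondrial UMIs (0.178). In lymphatic endothelial-like cells 3 genes fell. Among them was Mmp3, the protease stromelysin (38.5 ± 6.05 to 4.77 CPM, log2 fold change −2.86, SE 0.36, edgeR adjusted p = 0.00146), called in all 15 alternatives. The HFpEF sums held 1, 4 and 6 Mmp3 UMIs. Mmp3 was also a leading gene of a fibroblast cluster, with a log2 fold change of −0.76 in fibroblast-like cells (edgeR adjusted p = 0.618). Fibroblast contaminating transcripts overlapped in this class (0.418% ± 0.153 of UMIs in CON, 0.375% ± 0.0812 in HFpEF). Carry-over of Mmp3 was not tested. Fmo2, a flavin monooxygenase, fell as well (240 ± 40.7 to 103 CPM, −1.24, SE 0.19, 0.0218). Its call ended without HFpEF replicate 2 (0.0630), HFpEF replicate 3 (0.140) or CON replicate 2 (0.125) and with Scrublet-called cells kept (0.188). In pericyte-like cells Hlf rose with Angptl4 (74.5 ± 21.6 to 197 CPM, log2 fold change 1.44, SE 0.24, edgeR adjusted p = 0.0424), and its call ended without HFpEF replicate 1 (0.0655), 2 (0.418) or 3 (0.242) or CON replicate 1 (0.332), with thinned sums (0.113), with at most 10% mitochondrial UMIs (0.309) and with at least 1000 UMIs per cell (0.0910). With a replicate block edgeR called 1 gene in this class, so the call of Hlf, of Angptl4 or of both ended there. Smooth muscle-like cells had 0 higher genes and 1 lower by edgeR, Inmt, a methyltransferase (16.9 ± 3.45 to 3.66 CPM; −2.22, SE 0.20, 0.0142). Inmt was named after its value was seen, because its mean level lies under the 20 CPM of the naming rule. The call ended without HFpEF replicate 1 (0.0804), 2 (0.0883) or 3 (0.0660) or CON replicate 3 (0.0527), with Scrublet-called cells kept (0.241) and at Leiden resolution 2 (0.141). It also ended with a replicate block, by which edgeR called 0 genes in this class. Inmt was also a leading gene of a fibroblast cluster, and fibroblast contaminating transcripts in smooth muscle-like cells fell from 0.477% ± 0.153 of UMIs in CON to 0.237% ± 0.0622 in HFpEF, without overlap. A cluster in which Scrublet called 40.1% doublets held 15.2% ± 10.7 of the analysed smooth muscle-like cells in CON and 3.34% ± 1.29 in HFpEF, also without overlap, and with at most 10% mitochondrial UMIs edgeR called 33 genes. In this class 1442 of 11777 tested genes had an unadjusted p under 0.05. Of its genes 18.4% did not overlap between the groups, where chance gives 10%, and this share was not tested. EdgeR called 0 genes in T-cell-like (329 at an unadjusted p under 0.05; DESeq2 0), monocyte-like (431; DESeq2 6) and neutrophil-like cells (266; DESeq2 10), and without CON replicate 3, whose monocyte-like and neutrophil-like cells were shallow (medians of 1936.5 and 1270.0 UMIs), it called 4, 23 and 29. Endocardial-like calls reached 17 without CON replicate 1 and pericyte-like calls 7 without CON replicate 2. Over the 9 classes 64 genes changed, 10 when Scrublet-called cells were kept.

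Shares of T-cell-like, B-cell-like, platelet-like and neutrophil-like cells did not overlap between the groups, and none passed the exact test after adjustment. T-cell-like cells made up 0.827% ± 0.179 of analysed cells in CON and 1.49% ± 0.131 in HFpEF, B-cell-like cells 2.02% ± 0.626 and 3.70% ± 0.820, and platelet-like cells 0.458% ± 0.178 and 1.76% ± 0.624. Neutrophil-like cells made up 2.16% ± 0.805 in CON and 0.728% ± 0.307 in HFpEF (SD, n = 3 libraries per group). Each of these 4 had the smallest possible p (exact two-sided permutation test p = 0.1; adjusted p = 0.4 over 18 shares). The neutrophil-like class pooled 2 clusters: in CON replicate 3 83.2% of its cells lay in the shallower one, against 3.85% to 6.82% in the HFpEF libraries, and the other cluster alone overlapped (2.86%, 1.36% and 0.294% of analysed cells in CON, 0.459%, 0.997% and 0.595% in HFpEF). Shares of NK and innate lymphoid-like cells overlapped as well (0.573% ± 0.275 and 0.601% ± 0.158, exact permutation p = 0.9). The platelet-like class was 1 cluster in which 12 fibroblast markers and 5 platelet markers were detected. At Leiden resolution 2 the platelet-like shares overlapped (0.213% ± 0.149 and 0.474% ± 0.328). There 111 CON and 461 HFpEF cells of this class, 55.2% and 73.3% of it, joined the fibroblast-like cells. Fibroblast-like cells made up 42.1% ± 18.1 and 51.9% ± 10.4 (exact permutation p = 0.5); without CON replicate 3 the difference was −0.693 percentage points. Endothelial-like cells made up 9.98% ± 2.39 and 10.1% ± 2.92 (exact permutation p = 0.8).

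Macrophage-like cells made up 0.863% ± 0.209 of CON and 2.40% ± 1.74 of HFpEF cells (exact permutation p = 0.2), with 4.34% in HFpEF replicate 2. EdgeR's test of cell counts called neutrophil-like (log2 fold change −1.56, SE 0.41, adjusted p = 0.00262), platelet-like (2.02, SE 0.52, 0.00262) and macrophage-like cells (1.41, SE 0.45, 0.0154), and not B-cell-like or T-cell-like cells (both 0.238). The platelet-like call is of the cluster with fibroblast and platelet markers given above, so it does not show more platelets. Red cell lysis and dead cell removal came before capture, and CON replicate 3 had the shallow, largely unnamed cells given above, so shares can follow recovery. Of named cells alone, a denominator added after the data were seen, B-cell-like shares overlapped between the groups (2.84% ± 1.07 and 4.23% ± 1.05). Of named cells the endocardial-like (2.15% ± 0.423 and 1.41% ± 0.0608) and lymphatic endothelial-like shares (3.15% ± 1.03 and 1.59% ± 0.474) were lower in each HFpEF library than in each CON library, which was not so over all cells.

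**Figure D4:**
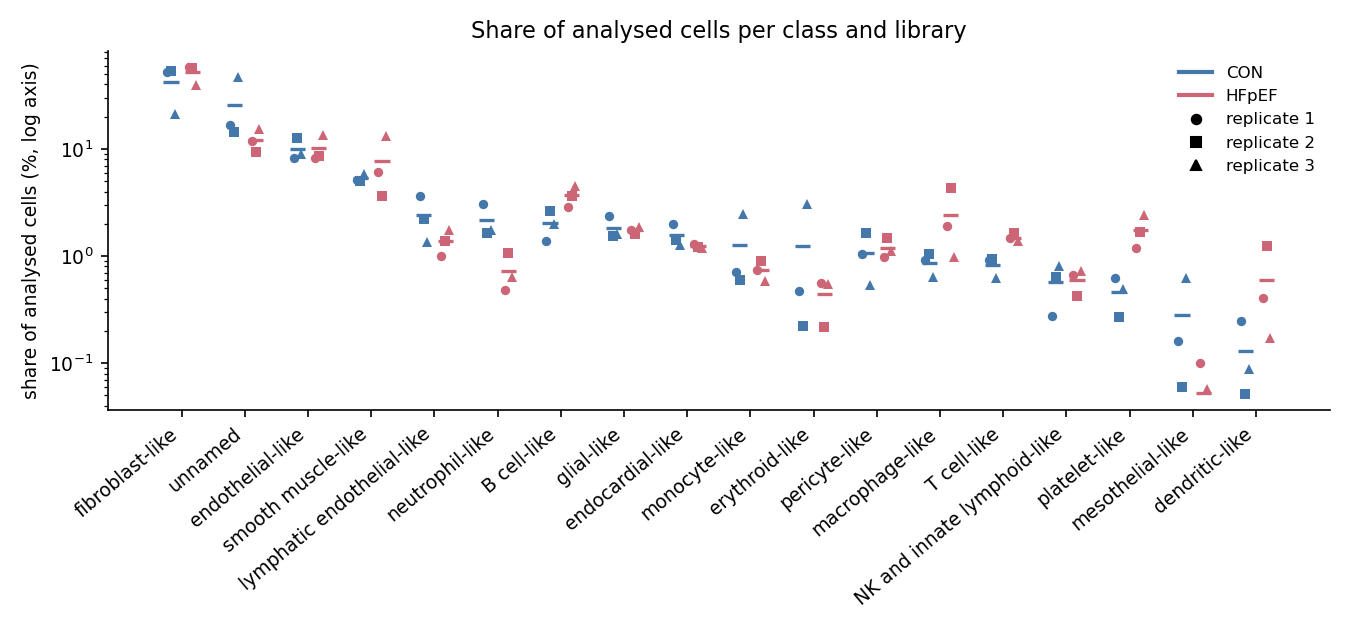
Share of analysed cells (y axis, percent, log scale) per class, with 1 point per CON or HFpEF library; mesothelial-like cells of HFpEF replicate 2, at 0, are not drawn. Neutrophil-like cells lay between 1.65% and 3.09% in CON and between 0.477% and 1.07% in HFpEF.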

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

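The tests of free RNA and of the cluster mix below were chosen after the Angptl4 values were seen, and the free RNA test was changed 2 times after its values were seen, from UMIs per cell against B-cell-like cells, to the higher of B-cell-like and T-cell-like cells, to shares of cells. Angptl4 was higher in HFpEF in cell groups that enter no comparison of the report. In platelet-like cells it averaged 48.0 ± 35.7 CPM in CON and 118 ± 26.4 CPM in HFpEF (SD, n = 3 libraries per group), the lowest HFpEF library at 88.8 CPM and the highest CON library at 85.6 CPM. This class was 1 cluster in which 12 fibroblast markers and 5 platelet markers were detected, and the rise is not shown to lie outside fibroblasts. Of its cells 111 in CON and 461 in HFpEF joined the fibroblast-like class at Leiden resolution 2, with Angptl4 at 40.0 and 129 CPM over the pooled cells of each group. Those that stayed platelet-like, 90 and 168 cells, held 8 and 9 Angptl4 UMIs, or 42.1 and 42.8 CPM. In unnamed cells it averaged 22.4 ± 1.37 CPM in CON and 68.6 ± 15.3 CPM in HFpEF. Platelet-like cells came to few per CON library and unnamed cells are a mixture, so neither was tested gene by gene.

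The pattern of Angptl4 across classes was weighed against free RNA and a changed mix of fibroblast clusters. The level of free RNA was read from the share of B-cell-like and T-cell-like cells, which should lack the gene, with an Angptl4 UMI at 1000 UMIs per cell (0.303%, 0.742% and 0.992% in HFpEF replicates 1, 2 and 3); their mean UMIs were not used, since in HFpEF replicate 3 single cells held 40 of 67 B-cell-like and 41 of 49 T-cell-like UMIs. The lowest ratio over the HFpEF libraries of a class's lower 95% limit to the upper limit of that share was taken. This ratio was 9.04 in the endothelial-like cluster with the highest CON level, which argues against free RNA as the whole source there. In pericyte-like and glial-like cells the ratio was 2.22 and 1.69. Fibroblast contaminating transcripts made up 1.26% and 0.826% of HFpEF UMIs in these 2 classes, and 0.166% and 0.412% in B-cell-like and T-cell-like cells. Free RNA may thus be higher in these 2 classes than in B-cell-like and T-cell-like cells, and it is not excluded as the source there. The ratio was 0.711 in lymphatic endothelial-like cells, 0.552 in smooth muscle-like cells and 0.361 in the other endothelial-like clusters, where the limits overlap and free RNA cannot be told apart from expression. With the 6 fibroblast clusters weighted equally, Angptl4 was 22.7 ± 5.56 CPM in CON and 86.5 ± 18.5 CPM in HFpEF, a fold of 3.82, which argues against the mix of clusters as the whole cause; the diet, L-NAME and the time of feeding may each act on this gene and were not separated by the design.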

How the results depend on the processing

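The share of named cells was chosen after the data were seen. Of the values recomputed for single genes 2761 kept their direction and side of the threshold, 107 gained and 57 lost a call and 4 reversed; for gene lists 206 kept both, 7 gained and 94 lost a call and 8 reversed; for class shares 101 kept both and 6 reversed; of the counts and shares that answer a comparison 112 stayed within their limits and 33 moved. By the DESeq2 Wald test 9 genes were higher and 22 lower in fibroblast-like, 5 and 8 in endothelial-like, 4 lower in macrophage-like cells, 293 changed in the other classes, and Angptl4 in fibroblast-like cells stood at 1.91 with an adjusted p of 2.28e-18. Without the low-count filter the counts were 1 and 2, 58 and 48, 20 and 25, and 665, and Angptl4 stood at 1.91. With sums thinned to the smallest library 1 fibroblast gene was higher, 1 endothelial gene lower, and Angptl4 stood at 1.89 (adjusted p = 0.0490). With a replicate block 17 endothelial genes were higher and 18 lower, and 138 changed in the other classes; deviations of libraries of the same number correlated at 0.217 to 0.281 across genes in endothelial-like, −0.132 to 0.251 in fibroblast-like and −0.360 to −0.00122 in macrophage-like cells, and in endothelial-like and T-cell-like but not in the other 10 classes each same-number correlation stood above all others, a hint from the data and not the design, so pairing stays open. With Scrublet-called cells kept 10 genes changed in the other classes, and Col8a1 (0.0769) and Vcan (0.0314) reversed in macrophage-like cells. At most 10% mitochondrial UMIs gave 1 endothelial gene lower and an endothelial share difference of −0.485 points, and of named cells it was −2.21. With an estimated correlation 0 lists were called and by fry's directional test 0; edgeR on cell counts called 3 classes. With 1 library left out, ranges were 0 to 1 gene higher in fibroblast-like cells, 0 to 4 higher and 0 to 7 lower in endothelial-like cells, 0 to 1 lower in macrophage-like cells, 24 (without HFpEF replicate 3) to 149 (without CON replicate 3) in the other classes, 1.76 to 2.04 for Angptl4 in fibroblast-like cells and 0 to 1 for the interaction. Tnc in fibroblast-like cells ran from −0.0794 (without HFpEF replicate 2) to 2.87 and Col14a1 in macrophage-like cells from −0.65 to 0.0664 (without HFpEF replicate 2). Adjusted p-values ran from 0.0420 to 0.877 for fibroblast activation, 0.00202 to 0.981 for oxidative phosphorylation and 0.410 to 0.834 for the clock in fibroblast-like cells, 0.0143 to 0.879 for endothelial activation in endothelial-like cells, and 0.000529 to 0.457 for collagens in macrophage-like cells, each with a change of direction in at least 1 fit. The fibroblast share difference ran from −0.693 (without CON replicate 3) to 15.8 points and the endothelial from −1.52 to 1.53. The cause was not tested for any of these. In macrophage-like cells a simulated fold of 2 was recovered in 7.46% of genes, which limits what counts of 0 show there.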

Other observations

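The tests of the clock across classes, of CON replicate 3, of free RNA in glial-like cells and of the other splits were chosen after the result was seen. The test of falls in glial-like cells carried over from fibroblast-like cells first had a bound of −0.2 on the median alone, which the value passed by less than its spread; a bound of −0.5 on the lower quartile was added after the value was seen.

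In fibroblast-like cells the DESeq2 Wald test called genes that edgeR did not, and those named here were chosen after their values were seen. Fetub, a protease inhibitor of the cystatin family, had a log2 fold change of −1.51 (DESeq2 adjusted p = 2.37e-12, edgeR 0.0831). Gcat (−0.89), Abat (−0.84), Bckdhb (−0.71), Oxct1 (−0.62) and Ivd (−0.67) were lower at DESeq2 adjusted p from 0.00154 for Gcat and Abat to 0.0197 for Ivd (edgeR 0.618 to 0.822), and no list of genes like these was tested. The glucose uptake genes Hk2 (−0.74) and Slc2a1 (−1.19) were lower at DESeq2 adjusted p = 0.000593 and 0.00145 (edgeR 0.618 and 0.778), while Cpt1a was higher (0.69, DESeq2 2.94e-06, edgeR 0.195). Camera did not call the glycolysis list, which holds Hk2 and Slc2a1, in fibroblast-like cells. Bc1, a noncoding RNA, had log2 fold changes of −1.41 in fibroblast-like cells and −1.47 in endothelial-like cells (DESeq2 adjusted p = 1.13e-08 and 7.85e-07), and Ifitm1, an interferon-induced membrane protein, −1.59 and −2.31 (2.96e-07 and 0.000134).

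The 9 clock genes that moved in endothelial-like cells moved the same way in 82.4% of the pairs of gene and other class, 56 of 68. Agreement by class ran from 2 of 5 pairs in B-cell-like cells to 8 of 8 in glial-like cells. All classes come from the same libraries, so agreement is expected without the clock. In 67.6% of pairs 274 other genes with an unadjusted p as small agreed. Of 1000 drawn sets of 9 such genes 95% lay between 50% and 83.9%, a range that holds the 82.4% of the clock genes. Only 3.7% of the sets lay at or above that value. Another hour of tissue collection or of feeding thus cannot be told apart from an effect of the diet or of L-NAME by these pairs, and the labels state no hour. CON replicate 3 alone is argued against, since a median of 120% of the log2 fold change remained without it (83.9% to 141% over the 9 genes).

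Genes called lower in glial-like cells may come from less free RNA of fibroblast-like cells in the HFpEF libraries. The calls depend on doublet removal, since edgeR called 0 genes lower with Scrublet-called cells kept. The values below do not tell free RNA from doublets with fibroblast-like cells. Of the 35 genes, 30 (85.7%) had at least 2 times the CPM in fibroblast-like cells, against 5.62% of all genes tested, and the 8 fibroblast transcripts fixed beforehand had a median log2 fold change of −0.686 (SD 0.445), 6 of them lower. Among the 11 genes called higher 0 had such a level in fibroblast-like cells. A fall of the same genes in fibroblast-like cells carried over as free RNA is argued against as the whole cause, since it needs falls like those in glial-like cells (median −1.21) and the median there was −0.184 (quartiles −0.364 to −0.0124). In B-cell-like cells 10 of the 10 genes called lower had at least 2 times the CPM in fibroblast-like cells, against 16.6% of genes tested.

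The 6 libraries allow 10 splits of 3 against 3, too few to give a share under 0.05. The real split gave 0 genes in fibroblast-like cells and the highest other split 1; in endothelial-like cells 0 and 9; in macrophage-like cells 0 and 42; for the interaction 0 and 0; in each of these 4 cases 10 of 10 splits gave as many, as they must with a real count of 0, so this shows nothing about chance. In the other classes the real split gave 64 and the highest other 58, and 1 of 10 splits gave as many. For the gene lists the real split gave 32 calls and the other splits 16 to 33, with 2 of 10 splits giving as many. The count of list calls thus does not set the real groups apart. The 42 macrophage genes arose with HFpEF replicates 2 and 3 and CON replicate 1 on one side. This split was picked as the highest of 10, and no test of a structure of the samples other than the groups was run.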
